A study of Drosophila melanogaster with 8 samples.

How the data were processed

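RNA-seq libraries of Drosophila S2 cells were analysed from 4 deposited tables of values per gene, covering 8 libraries. Of these, 6 came from stable lines selected with G418 that carried wild-type or mutant Beaf, 3 per genotype. The labels describe depletion with 400 µg of double-stranded RNA for 5 days, and 1 library is labelled as CTCF knockdown and 1 as its control. The labels' protocols give 2 descriptions of the library preparation, both with Illumina TruSeq kits but with different kit numbers and amounts of RNA. The second states that poly-A selection was not done, the first says nothing of it, and which libraries each covers is not stated. CASAVA 1.8, BWA and HTSeq are named in the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so overlapping genes and near-identical copies such as Hsp70 and the histones are uncertain.

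The deposited columns of the mutant and knockdown libraries hold whole-number read counts per gene with no normalization visible in the values. The deposited columns of the wild-type and control libraries hold a signal, namely read counts multiplied by 1 factor per column and rounded. This was read from the values, since no label states it. The totals of the 2 columns of each table, unassigned reads included, differ by 157 to 466 reads, and the columns of wild-type libraries 1 and 2 and of the control skip whole numbers at a regular spacing. Division by factors of 1.234, 1.237 and 1.297 gave whole reads for 99.99% of positive values in wild-type library 1, 100% in wild-type library 2 and 99.97% in the control, against 81.0%, 80.8% and 77.1% by chance. Wild-type library 3 was scaled by a factor slightly below 1, since 137 genes share the value 24 against 87 and 79 at the neighbouring values. Its values could not be inverted and were used as deposited. Recovered gene reads were 1720616, 1528041 and 10963743 for wild-type libraries 1 and 2 and the control.

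Because rescaled values are not counts, the planned edgeR quasi-likelihood test was replaced as main test by limma-trend, a choice made after the values and edgeR's results had been seen. Values were scaled with TMM factors, filtered with filterByExpr and turned into log2 CPM with a prior count of 2, and p-values were two-sided and adjusted by Benjamini-Hochberg at 0.05. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. EdgeR, DESeq2 and limma-voom were run on recovered reads as alternatives, with wild-type library 3 as deposited, and edgeR also on the deposited values. Rows of unassigned reads were left out of library sizes and tests. Reads outside annotated features were 85.6% to 94.0% of each library of the Beaf lines, 8.05% of the control and 6.93% of the knockdown. Reads not aligned were 0.790% to 10.4% in the Beaf lines, 18.4% in the control and 45.1% in the knockdown.

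The libraries were compared before averaging. Chi-square per degree of freedom between replicates ranged from 2.34, for mutant libraries 2 and 3, to 38.1, so no pair was within sampling noise. Wild-type and mutant library 1 stood apart from the others of their genotype, with mutant library 1 on the first principal component (71.6% of the variance). The comparison of libraries 2 and 3 of each genotype, the edgeR fits, the prior counts of 0.5 and 5, the restriction to protein-coding genes, the estimated correlation for head-to-head genes and the CTCF rule on deposited values were added after the data had been seen. Limma-trend as main test, the tests on wild-type and mutant library 1 and some named genes were also chosen after that. The gene lists, the naming rule and the other alternatives were fixed before the data were examined. The column names carry no replicate number, so the numbers used here only name the table a column came from.

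Of 15438 genes in each table, 14606 (94.6%) matched a symbol, and 2810 were listed at 0 in all 8 libraries. Those at 0 made up 23.8% of the protein-coding genes that overlap another gene in the annotation used here (BDGP6.54, which need not be the authors') and 2.63% of those that do not. IDs without a match took 28.9% to 33.8% of gene values in the Beaf lines and 10.3% to 10.5% in the CTCF libraries. The 29 fixed lists held 767 entries, of which 714 matched. They cover insulator, cohesin and condensin, pausing, Polycomb, homeotic, dosage compensation, replication, mitosis, histone, ribosomal protein, heat-shock, unfolded protein response, immunity, JAK/STAT and JNK, RNA interference, hemocyte, ecdysone, detoxification, glycolysis, oxidative phosphorylation, lipid, proteasome, cytoskeleton and extracellular matrix genes. Markers of neuronal, muscle, gonadal, fat body and epithelial cells were included as other cell types. Lists with at least 5 tested members were tested with limma's camera, with a preset correlation of 0.01, adjusted over 27 lists. Lists were also tested with an estimated correlation and with fry. With an estimated correlation camera takes its degrees of freedom from the few libraries, so a list can hardly pass after adjustment. A large adjusted p there therefore does not show that correlation between genes made the preset call. Head-to-head genes were taken from the annotation, within 500 bp. The planned class of promoters with clustered CGATA motifs was not run, because no genome sequence was used here.

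Genes were named by a rule. BEAF-32 came first. Then, among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, the 10 largest rises and 10 largest falls were taken. By chance 33.3% of genes do not overlap with 2 libraries against 2, and 10% with 3 against 3. Up to 4 members per list past the threshold, and the insulator list as a group, were added. For CTCF the rule took CTCF, the 10 highest and 10 lowest ratios, and up to 3 members per list past 2-fold. The levels of roX1, Glt, Hml, Col4a1, zfh2, blanks, Hsp70Aa and Cp190 in single libraries, Gart, and list members beyond the first 4 were chosen after their values had been seen.

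CTCF ratios were log2 ratios of TMM-scaled CPM with a prior count of 5 on recovered reads, for genes with at least 50 reads in the larger library and with a size rule of 2-fold. With 1 library per group no p-value was computed. Intervals are 95% exact intervals and cover counting error only. A list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression.

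The steps were tested on simulated data drawn from the real means with 200 of the better-covered genes changed. All simulated Beaf libraries had the same dispersion, 0.0748 for 6 libraries and 0.00286 for libraries 2 and 3. The departure of wild-type and mutant library 1 was therefore not simulated, and the shares below need not hold for the real libraries. For 6 libraries, over 6595 genes, limma-trend recovered 4.50% of 1.5-fold, 37.3% of 2-fold and 98.5% of 4-fold changes, with 2.10% of calls false. For libraries 2 and 3, over 5841 genes, it recovered 86.6%, 97.0% and 100%, with 2.60% of calls false. The CTCF rule recovered 100% of 4-fold changes, with 1 other gene past it. Its simulated libraries differed by sampling of reads alone, and a 4-fold change lies well past the 2-fold rule. This outcome was therefore set beforehand and gives no rate of false genes for the real pair. Alternatives covered scaling, filters, tools, thresholds, prior counts, a replicate block and leaving out each library.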

Results

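RNA was sequenced from S2 cells, a Drosophila line derived from late embryos with features of macrophage-like hemocytes. Stable lines carried vectors for wild-type or mutant Beaf (BEAF-32, FBgn0015602), an insulator protein that binds near promoters, and each genotype was represented by 3 libraries. In addition, 1 library came from cells treated with double-stranded RNA against CTCF (FBgn0035769), another insulator protein, and 1 from its control. The labels do not say that the libraries of a genotype came from separate cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. Camera's p-values with a preset correlation set list members against other genes. They take genes as units, which are not independent, and do not measure the spread between cultures. The series describes triplicates of a wild-type and a mutant line. Genotype therefore cannot be told apart from other differences between these lines, including their level of BEAF-32 RNA. Libraries of the Beaf lines are numbered by the deposited table that holds them, with 1 wild-type and 1 mutant library in each of 3 tables. The values deposited for genes summed to between 1544063 and 2122627 per library in the Beaf lines. Between 85.6% and 94.0% of all reads in those libraries fell outside annotated features, against 8.05% in the CTCF control and 6.93% in the knockdown. The control held 10963743 gene reads, recovered from its rescaled values, and the knockdown 9267319.

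The first comparison asked how expression differed between cells with mutant and with wild-type Beaf. BEAF-32 RNA, to which the endogenous and the transfected gene both contribute, averaged 380 ± 322 CPM in wild-type (SD, n = 3) and 1623 ± 242 CPM in mutant libraries (SD, n = 3). Wild-type library 1 held 25.5 CPM of it, against 462 and 654 CPM in wild-type libraries 2 and 3, and the mutant libraries held 1415, 1565 and 1888 CPM. The CTCF control, from another treatment and a separate table, held 59.6 CPM, so the BEAF-32 level of the library labelled wild-type library 1 does not by itself show a transfected gene. The hemocyte genes Hml (hemolectin, a clotting protein) and Glt (glutactin) were also far lower in wild-type library 1, at 220 and 8.17 CPM, than in wild-type libraries 2 and 3, where Hml stood at 1314 and 1421 CPM and Glt at 630 and 668 CPM. Mutant library 1 departed in other genes: the transcription factor gene zfh2 was at 93.4 CPM there against 1075 and 1078 CPM in mutant libraries 2 and 3, while Hsp70Aa, a heat-shock chaperone gene, was at 1283 CPM against 190 and 179 CPM. Its rank correlation across genes with the other mutant libraries was 0.833 and 0.830, where those 2 correlated at 0.981.

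**Figure D1:**
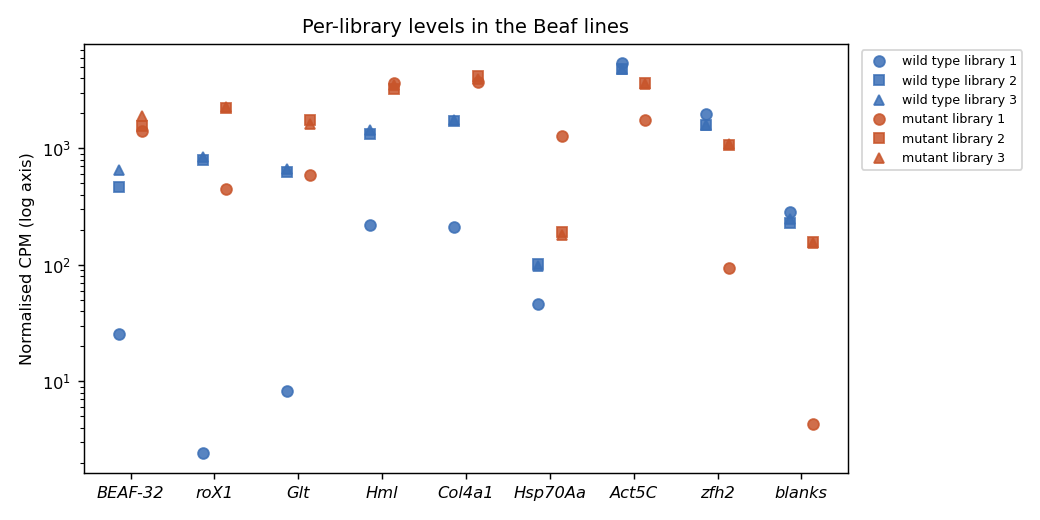
Normalised CPM on a log axis for 9 genes in the 6 libraries of the Beaf lines, with wild-type libraries in blue, mutant libraries in orange and a symbol for each library number. Wild-type library 1 lies lowest for BEAF-32 at 25.5 CPM, and mutant library 1 lies lowest for blanks at 4.28 CPM.

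With all 6 libraries, limma-trend found 0 of 6564 genes past a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.214. At an unadjusted p under 0.05 limma-trend gave 1274 genes. Limma-voom and edgeR's quasi-likelihood test, on recovered reads or on the deposited values, also found 0 genes, while DESeq2 called 220, of which 219 were higher in the mutant. The gene that DESeq2 called lower was Gart, which encodes a purine synthesis enzyme. For BEAF-32 itself the log2 fold change was 3.01 with an SE of 1.11 and limma's adjusted p was 0.231, and the log2 fold change ranged from 1.54 to 3.84 when any 1 library was left out. Without mutant library 1, limma called 471 genes, 286 higher and 185 lower. Of the genes DESeq2 called, 205 had the same direction and passed limma's threshold in libraries 2 and 3 of each genotype. Those libraries also served for DESeq2's calls, which favours such agreement.

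Because both libraries numbered 1 departed from the others of their genotype, the comparison was repeated on the 2 wild-type and 2 mutant libraries numbered 2 and 3, a choice made after the values had been seen. Libraries 2 and 3 were kept because they lay close together within a genotype, so the p-values measure a spread that this choice narrowed. EdgeR's common dispersion was 0.00286 in them, against 0.0748 with all 6 libraries. In libraries 2 and 3 Hml and Glt, the collagen IV gene Col4a1, the chaperone gene Hsp23 and the apoptosis gene hid rose in the mutant. The proteasome gene Rpt2 and the glycolysis gene Pfk fell. BEAF-32 rose from 558 ± 136 to 1726 ± 228 CPM (SD, n = 2 each), a log2 fold change of 1.64 with an SE of 0.11 and a limma adjusted p of 2.92e-09. The noncoding RNA roX1, which serves dosage compensation of the X chromosome, rose 2.73-fold with a limma adjusted p of 1.18e-11. In the libraries left out, roX1 (lncRNA:roX1) was at 2.40 CPM in wild type and at 444 CPM in the mutant, which is below the 791 and 839 CPM of wild-type libraries 2 and 3, and with all 6 libraries its log2 fold change of 3.29 had a limma adjusted p of 0.360 and ranged from 0.67 to 4.61 when any 1 library was left out. limma-trend called 975 of 6619 genes, 618 higher and 357 lower, edgeR called 1065 on recovered reads, and DESeq2 called 180. Only 217 of limma's calls were at least 2-fold, 206 higher and 11 lower. Mutant library 1, which was left out, lay above the mean of wild-type libraries 2 and 3 in 544 of the 618 genes that rose. It lay below that mean in 324 of the 357 that fell. The same wild-type libraries served for the calls, which favours such agreement, and the share among all tested genes was not computed.

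By the rule fixed for naming genes, the largest rises were those of CG14931 (log2 fold change 2.59), CG17350 (2.32), Itgbn (2.20), an integrin beta subunit of phagocytes, Cyp6t1 (1.98), a cytochrome P450, Prip (1.92), a water channel, Agpat4 (1.91), an acyltransferase, CG13405 (3.48-fold), FBgn0052822 (1.77), CG4301 (1.73) and dysf (1.72), a transcription factor of the tracheal system. CG14931 had no count in any wild-type library and 5.66 and 5.71 CPM in mutant libraries 2 and 3, so its fitted fold depends on the prior count. The largest falls were those of Bhmt (−1.49), Mco4 (−1.44), FBgn0030646 (−1.36), mRpS18C (−1.27), a mitochondrial ribosomal protein gene, CG2854 (−1.24), CG11590 (−1.17), CG7544 (−1.13), mRpL40 (−1.13), also mitochondrial ribosomal, Pop5 (−1.08), an RNase P subunit, and CG9837 (−1.08). Among these 20 genes limma's adjusted p ranged from 0.000184 for dysf to 0.0460 for mRpS18C. The most extreme genes were scarce, and none of the 20 exceeded 30 CPM in mutant libraries 2 and 3. Mutant library 1 lay above the mean of wild-type libraries 2 and 3 in all 10 of the rises, but below it in only 5 of the 10 falls, and it held more CG9837 than any wild-type library and CG7544 at 12.1, CG2854 at 10.7, mRpL40 at 10.7 and Bhmt at 7.85 CPM. With all 6 libraries the log2 fold changes of CG2854 and CG9837 were −0.57 and −0.49 (limma adjusted p = 0.488 and 0.547). Mutant library 1 also held reads in genes silent elsewhere, so its level says little about genes this scarce.

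Hemocyte markers had the smallest camera p of the lists in libraries 2 and 3: 14 of 20 tested members rose and 2 fell, with 14 and 4 when adjusted over the list alone. NimB5 rose 3.06-fold, the scavenger receptor gene Sr-CI 3.04-fold, Glt 2.59-fold and Hml 2.44-fold, while the ferritin gene Fer1HCH and Tig fell, by log2 fold changes of −0.46 and −0.20. Mutant library 1, which was left out, held Hml at 3660, Col4a1 at 3723 and Sr-CI at 119 CPM, above wild-type libraries 2 and 3, but Glt at 590, Pxn at 380, SPARC at 531, NimC1 at 9.99, He at 7.13 and NimB5 at 4.99 CPM, below their means there of 649, 568, 596, 23.5, 13.4 and 5.59 CPM. Camera with a preset correlation gave the list an adjusted p of 1.89e-11 (up), and the adjusted p was 0.293 with an estimated correlation. The extracellular matrix list, which shares genes with the hemocyte markers, had 6 of 14 members up and 2 down, with 7 and 3 when adjusted over the list alone. Its collagen IV genes Col4a1 and vkg rose 2.35-fold and 2.23-fold, and the matrix metalloprotease gene Mmp2 rose 1.93-fold (camera adjusted p = 0.00216, and adjusted p = 0.293 with an estimated correlation).

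Heat-shock genes rose in 9 of 17 tested members and fell in 0, with 11 and 0 when adjusted over the list alone (camera adjusted p = 5.35e-06, and adjusted p = 0.293 with an estimated correlation). Hsp23 rose 2.27-fold, Hsp26 2.01-fold and Hsp70Aa 1.85-fold, but the Hsp70 copies are nearly identical and their reads cannot be assigned with certainty. The JAK/STAT and JNK list had 5 members up and 1 down among 14, the same counts when adjusted over the list alone. Its apoptosis gene hid rose 3.03-fold, the cytokine receptor gene et 2.99-fold and the JNK phosphatase gene puc 1.59-fold, and the TNF gene egr fell (camera adjusted p = 0.0185, and adjusted p = 0.293 with an estimated correlation). Ecdysone response genes rose in 5 of 12 and fell in 1, with 6 and 2 when adjusted over the list alone. The nuclear receptor gene Eip78C rose 1.74-fold and the transcription factor gene Eip74EF 1.55-fold (camera adjusted p = 0.0384, and adjusted p = 0.315 with an estimated correlation). With the deposited table as a replicate block camera no longer called this list (adjusted p = 0.086).

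Among marker lists of other cell types, camera with a preset correlation called neuronal and muscle genes but not epithelial and gonadal genes. Of 7 tested neuronal markers 3 rose, the calcium channel gene cac 3.08-fold, nrv3 2.59-fold and CadN 1.81-fold, and none fell (camera adjusted p = 0.00392, and adjusted p = 0.293 with an estimated correlation). Of 5 muscle markers 3 rose, Mf 2.64-fold, bt 2.28-fold and Mef2 1.42-fold (camera adjusted p = 0.00808, and adjusted p = 0.320 with an estimated correlation). Adjusted over the list alone, 3 neuronal markers rose and 0 fell, and 3 muscle markers rose and 1 fell. Epithelial markers had 3 up and 2 down of 14, also when adjusted over the list alone, with the polarity genes sdt and crb up 2.55-fold and 2.24-fold (camera adjusted p = 0.914). Gonadal markers had 2 up and 1 down of 7, and 3 and 2 when adjusted over the list alone (camera adjusted p = 0.553). The fat body genes Lsp1gamma and Apoltp rose in a list of 3 tested members, too few for a list test. Mutant library 1 held Apoltp at 369.5 CPM, below the 505 and 558 CPM of wild-type libraries 2 and 3. It held Lsp1gamma at 37.1 CPM, above their 10.9 and 12.7 CPM.

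Of 72 cytosolic ribosomal protein genes 18 fell and 0 rose, with 19 and 0 when adjusted over the list alone. Among them were RpL28, with a log2 fold change of −0.39, and RpL36, with −0.34 (camera adjusted p = 2.37e-08, and adjusted p = 0.315 with an estimated correlation). Mutant library 1 lay below the mean of wild-type libraries 2 and 3 in only 7 of the 18. Proteasome subunits fell in 7 of 30, among them Prosbeta4 (−0.65) and Rpt2 (−0.47), and glycolysis genes in 5 of 13, among them Ldh (−0.86) and Pfk (−0.67). Adjusted over the list alone, 7 members of each of these lists fell. Mutant library 1 lay below that mean in all 7 of the proteasome genes that fell, but in only 3 of the 5 glycolysis genes. It held Ldh at 41.4 CPM, above each wild-type library. Camera's adjusted p was 1.23e-05 for the proteasome and 0.000329 for glycolysis, and the adjusted p was 0.293 with an estimated correlation for both.

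Mitosis genes fell in 5 of 29, among them the spindle checkpoint gene mad2 (−0.90) and the kinesin gene ncd (−0.44), with 6 when adjusted over the list alone. The replication list had 1 of 23 down, the ribonucleotide reductase gene RnrL (−0.37), and oxidative phosphorylation had 3 of 27 down, among them Cyt-c1 (−0.57), with the same counts when adjusted over each list alone. Replication-dependent histones had 3 of 112 down, and 0 when adjusted over the list alone, and these repeated genes share reads. Camera's adjusted p was 0.000276 for mitosis, 0.0109 for replication, 0.00103 for oxidative phosphorylation and 0.00848 for histones. With an estimated correlation the adjusted p was 0.293 for the first 3 and 0.320 for histones. The cytoskeleton list had 5 down, among them Act5C (−0.41), and 2 up of 18, with 6 and 3 when adjusted over the list alone (camera adjusted p = 0.0460, and adjusted p = 0.433 with an estimated correlation).

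**Figure D2:**
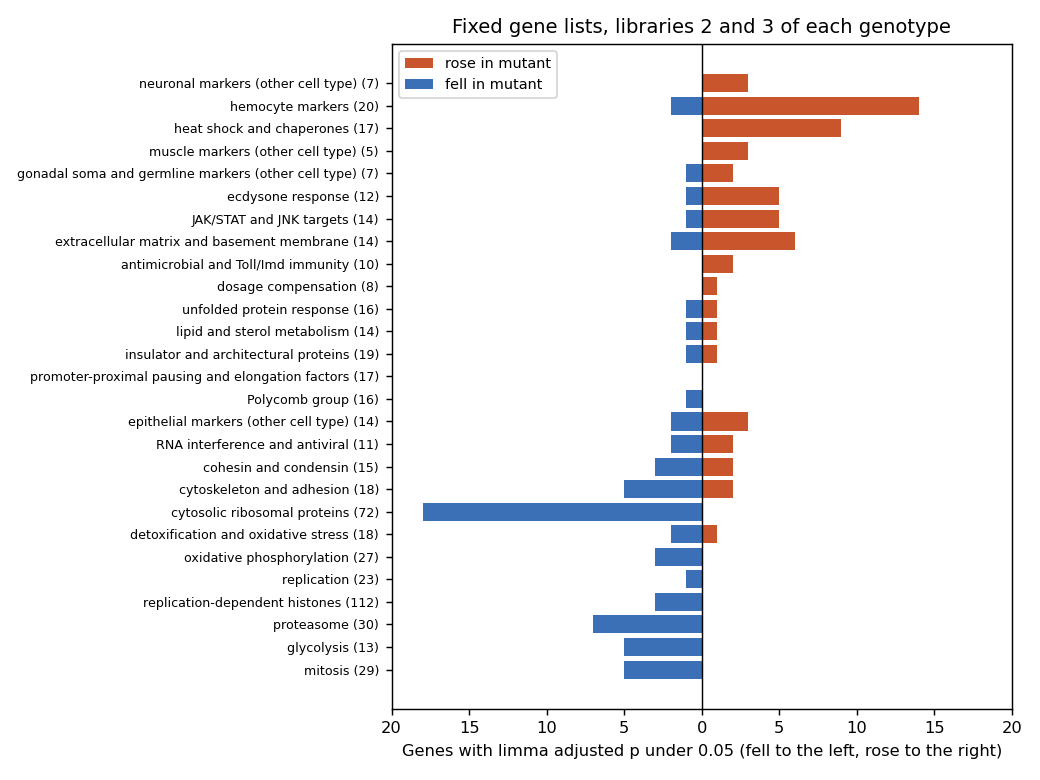
Number of genes of each fixed list with a limma adjusted p under 0.05 in libraries 2 and 3 of each genotype, fell to the left and rose to the right, with the number of tested members in parentheses and lists ordered by median log2 fold change. Hemocyte markers have 14 genes to the right and ribosomal protein genes 18 to the left.

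Across all 6 libraries camera called 11 of 27 lists, 5 up and 6 down, where splits that mix the genotypes called 4 to 10. With an estimated correlation camera called 0, with a smallest adjusted p of 0.498, and fry called 0. The lists higher in the mutant were heat shock (adjusted p = 0.000565), JAK/STAT and JNK (0.0284), hemocyte (0.00286), ecdysone (0.0284) and neuronal genes (0.00222). Those lower were replication, mitosis, histones, glycolysis, oxidative phosphorylation and the proteasome, with adjusted p from 2.03e-07 for the proteasome to 0.0284 for glycolysis. Without mutant library 2 camera no longer called JAK/STAT and JNK (adjusted p = 0.0785), hemocyte (0.0520) and glycolysis genes (0.124), the first and last of which were also lost without mutant library 3, and without wild-type library 1 it no longer called ecdysone genes (0.0681). The ribosomal proteins were not called by camera (adjusted p = 0.797), but without mutant library 1 they were lower with an adjusted p of 2.46e-07. No list member passed limma's threshold over all genes, and adjusted over the list alone JAK/STAT and JNK had 4 members up, muscle 3, RNA interference 2, hemocyte 2 up and 1 down, and neuronal, gonadal, detoxification and matrix 1 up each.

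Other insulator proteins differed little from wild type in libraries 2 and 3. Besides BEAF-32, 1 of 19 tested members of the insulator list passed limma's threshold, Dref (−0.41), with an adjusted p of 0.0450, and adjusted over the list alone BEAF-32 remained as 1 member up and 0 down (camera adjusted p = 0.913). CTCF had a log2 fold change of −0.25 (limma adjusted p = 0.459). Cp190, a cofactor of several insulator proteins, stood at 187 and 184 CPM in mutant libraries 2 and 3 and between 189 and 198 CPM in the wild-type libraries, but at 917 CPM in mutant library 1. Cohesin and condensin genes had 2 up, wapl and vtd, and 3 down, among them barr, with 2 and 4 when adjusted over the list alone (camera adjusted p = 0.159). The Polycomb list had 1 down, pho, the dosage compensation list 1 up, roX1, and the pausing list 0 members past limma's threshold, with camera adjusted p of 0.804, 0.119 and 0.898. RNA interference genes went both ways, with the piwi-family genes aub and AGO3 up 2.55-fold and 1.83-fold and the double-stranded RNA binding gene blanks down (−0.63), and camera gave an adjusted p of 0.919. The unfolded protein response list had 1 up, Cnx99A, and 1 down, crc, and immunity had the NF-kappaB genes Dif and dl up. Detoxification had cnc up and GstD1 and Cat down, and lipid metabolism had LpR2 up and ACC down. Adjusted over the list alone, these counts were the same except for 2 lipid genes up and 0 Polycomb genes down. Camera's adjusted p for these 4 lists was 0.670, 0.553, 0.389 and 0.991. For the insulator, pausing, RNA interference and epithelial lists the median log2 fold change was below 0 while the mean and camera's direction were above it. Of the homeotic genes 3 were tested, with log2 fold changes not past limma's threshold.

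Genes whose start lies head to head with another within 500 bp, a setting in which BEAF-32 often binds, had a median log2 fold change of −0.11 over 2702 genes in the 6 libraries, against 0.04 in 3374 other protein-coding genes (camera p = 0.000750, and p = 0.0266 with an estimated correlation). Splits of the 6 libraries that mix the genotypes gave a camera p as small as 0.00524. In libraries 2 and 3 the medians were −0.07 and 0.03 (camera p = 0.00177, and p = 0.00612 with an estimated correlation). There 101 of 2724 head-to-head genes rose (3.71%) and 134 fell (4.92%), while 438 of 3405 other genes rose (12.9%) and 186 fell (5.46%), so the 2 groups differed mainly in their share of rises.

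The second comparison asked what changed after depletion of CTCF for 5 days, with 1 library per group and so no test or replicate check. CTCF fell from 607 recovered reads in the control to 105 in the knockdown, that is from 56.6 to 11.1 CPM, a log2 ratio of −2.30 (95% interval −2.67 to −2.05). By a size rule of at least 2-fold and 50 reads in the larger library, 25 genes were higher and 19 lower of 6770, a balance that turned to 10 higher and 13 lower with a minimum of 200 reads. The lowest were CG3358 (−4.03) and sgll (−3.89), which encodes a vitamin B6 oxidase, and then, after CTCF, the heat-shock copies Hsp70Bbb (−1.95), Hsp70Bb (−1.92) and Hsp70Ba (−1.91), CG12236 (−1.77), CG13692 (−1.59), Hsp70Bc (−1.56) and Hsp70Ab (−1.33). The highest were IFT52 (3.33), an intraflagellar transport gene with 8 control and 114 knockdown reads, the snRNA:U2:34ABa (2.34), CG34033 (2.15), FBgn0085364 (2.08), CG6126 (1.84), the muscle myosin gene Mlc2 (1.62), the antimicrobial peptide gene Mtk (1.61), CG33774 (1.60), the piRNA gene piwi (1.47) and CG6357 (1.36).

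**Figure D3:**
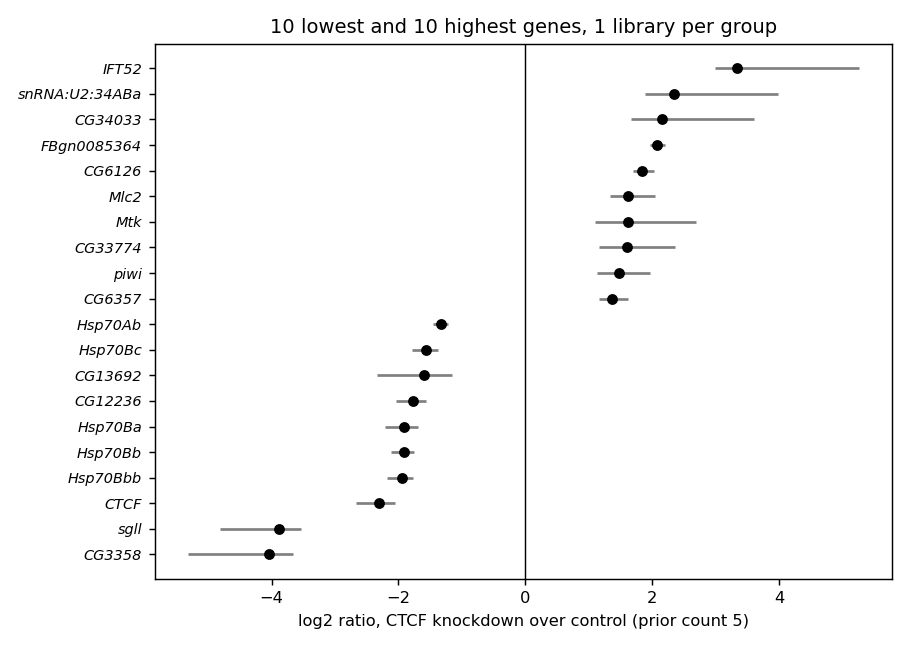
Log2 ratio of CTCF knockdown over control for the 10 lowest and the 10 highest genes, with points that include a prior count of 5 and lines for the 95% binomial interval of the reads without it, which covers counting error only. CG3358 lies lowest at −4.03 and IFT52 highest at 3.33.

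The same rule set 44 genes apart between knockdown and control, which is 0.650% of the genes with enough reads. Between replicate libraries of the Beaf lines it set 2 genes apart in wild-type libraries 2 and 3 and 2 in mutant libraries 2 and 3, and from 45 to 1347 in the pairs that hold a library numbered 1. Thinned to the mean depth of the Beaf libraries, the knockdown and its control differed in 19 genes, 7 higher and 12 lower. Intervals cover counting error only.

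List medians describe these 2 libraries and cannot separate the knockdown from a difference between libraries, and genes of a list are not independent. Of the hemocyte, matrix and detoxification lists 0 members passed the size rule. All 20 hemocyte markers had log2 ratios below 0, with a median of −0.36, under the median of every random list of matched expression among 10000. The matrix list had a median of −0.39, also below all random lists, and the heat-shock list −0.22 at percentile 0.01, with 7 members at least 2-fold lower. Detoxification genes had a median of 0.30, above all random lists, glycolysis genes 0.13 at percentile 99.96, immunity genes 0.15 at percentile 99.39 with Mtk and AttD at least 2-fold higher, muscle markers 0.15 at 98.99 and oxidative phosphorylation 0.04 at 98.99. The insulator list, which holds CTCF, had −0.12 at percentile 1.76, and the pausing list −0.13 at 1.26. BEAF-32 had a log2 ratio of 0.12 (95% interval −0.04 to 0.28). In all, 26 lists had enough members, and 10 of them lay outside the central 95% of random lists, 5 above and 5 below. The homeotic, histone and fat body lists had too few members with 50 reads for a percentile.

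The last comparison set both perturbations side by side, which share no library. Across 6173 genes, which are not independent replicates, the fold changes of CTCF knockdown and of the Beaf mutant in 6 libraries had a Spearman correlation of −0.045. With libraries 2 and 3 it was −0.012 across 6229 genes. Of 25 genes past the CTCF size rule that were tested there, 9 were lower in the knockdown and rose in the mutant, against 1.40 expected for independent lists. Of these, 7 are Hsp68 and the near-identical Hsp70 copies, which share reads and so count 1 family several times, and the others are CG12236 and mt:ND2. Another 4 were higher in the knockdown and rose in the mutant, against 0.940 expected, 2 were lower and fell, against 0.810, and 0 were higher and fell, against 0.540.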

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

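Both results here concern reads the aligner did not place, which no comparison of the report uses, and they were looked at only after the libraries had been seen. In the Beaf lines 8.55% ± 1.61 of reads were not aligned in mutant libraries (SD, n = 3) against 2.55% ± 1.53 in wild-type libraries (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. In the CTCF pair 45.1% of reads were not aligned in the knockdown against 18.4% in the control, with 1 library each. No explanation was tested for either difference.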

How the results depend on the processing

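Limma-trend as main test, the comparison of libraries 2 and 3, the edgeR fits, the prior counts of limma, the restriction to protein-coding genes, the estimated correlation for head-to-head genes and the CTCF rule on deposited values were chosen after the data had been seen. With 6 libraries, genes past the threshold numbered 0 under limma with each scaling, filter and prior count, under limma-voom and under edgeR, against 220 with DESeq2 and 975 in libraries 2 and 3. Leaving out each library gave 0 to 471, and the 471 came without mutant library 1. Genes meeting the naming rule numbered 219 with DESeq2, 973 in libraries 2 and 3 and 0 to 471 when leaving out each library. BEAF-32 passed only in libraries 2 and 3 (log2 fold change 1.64). There, the count fell to 503 at an adjusted p under 0.01, to 217 with a 2-fold minimum, because fewer genes can pass, and to 180 with DESeq2, and leaving out each library gave 660 to 897. Those fits leave 1 library in a group, which is assumed to vary like the other group, so they say little of stability.

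Camera with an estimated correlation called 0 lists with 6 libraries and 0 in libraries 2 and 3, a setting in which few libraries let little pass. Fry called 0 with 6 libraries and 15 in libraries 2 and 3, 9 up and 6 down. There fry did not call the ribosomal (adjusted p = 0.0712), histone (0.144) and cytoskeleton (0.101) lists. It called the cohesin and condensin (0.0165), dosage compensation (0.0189) and gonadal (0.0291) lists, which camera with a preset correlation did not. Of 101 named genes 99 kept their direction in each alternative. RpS21 turned negative with library size only (−0.013), upper quartile scaling (−0.012), no filter (−0.12) and libraries 2 and 3 (−0.35), and ranged from −0.37 to 0.24 when leaving out each library. Cp190 was at −0.059 in libraries 2 and 3 and from −0.052 to 1.10 when leaving out each library. The ribosomal list turned to lower in libraries 2 and 3 (adjusted p = 2.37e-08 by limma's camera), and its adjusted p ranged from 2.46e-07 to 0.987 when leaving out each library. Of lists that camera called with 6 libraries, JAK/STAT and JNK lost its call without mutant library 2 or 3 (adjusted p up to 0.0785), glycolysis likewise (up to 0.124), hemocyte without mutant library 2 (0.0520) and ecdysone without wild-type library 1 (0.0681). CTCF genes past the size rule numbered 29 with a prior count of 20, 23 with a minimum of 200 reads, 106 with a minimum of 10 and 190 at 1.5-fold, against 44. The correlation of both perturbations was −0.012 in libraries 2 and 3. Except where fewer libraries or another cutoff set the change, the cause was not tested.

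With the deposited table as a replicate block, limma called 0 genes with 6 libraries and 1230 in libraries 2 and 3. Without the block limma called 975 genes in libraries 2 and 3. Deviations of the wild-type and the mutant library of a table had correlations of −0.16, −0.12 and −0.08. Pairs from different tables gave nearly the same values among libraries 2 and 3. Wild-type library 2 had −0.121 with mutant library 3, and wild-type library 3 had −0.086 with mutant library 2. The correlations therefore cannot tell whether the number pairs libraries 2 and 3. The block ended the call of the ecdysone list in libraries 2 and 3 (adjusted p = 0.0860 by limma's camera) and made that of dosage compensation (adjusted p = 0.00146). The depth of the Beaf libraries limits scarce genes, and the class with CGATA motifs was not run.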

Other observations

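The tests on wild-type library 1 and mutant library 1 were chosen after the result was seen, and those on CTCF neighbours, overlap and splits before. Genes of the small chromosome 4 had a median log2 fold change of −0.42 over 67 genes with all 6 libraries, against medians from −0.14 on 2L to 0.03 on X among the large chromosomes. In libraries 2 and 3 the chromosome 4 median was −0.08, against −0.05 on 2L to 0.02 on 2R among the large chromosomes. There 12 of the 67 chromosome 4 genes rose and 5 fell past limma's threshold. Rises also outnumbered falls on each large chromosome. The difference between chromosomes was not tested. The genes that DESeq2 called with 6 libraries had a median of 113 CPM in mutant library 1, 39.8 CPM in mutant libraries 2 and 3 and 16.0 CPM in wild type.

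Wild-type library 1 lay beyond wild-type libraries 2 and 3, away from the mutants, in genes such as Glt, Hml and BEAF-32. It was the wild-type library farthest from the mutants in 76.6% of the genes called in libraries 2 and 3, a count that restates the pattern and decides nothing about genotype as its cause. A mixture of cell populations in different shares may underlie this and stays open. Positions were taken on a scale from wild-type library 1 at 0 to mutant libraries 2 and 3 at 1. Wild-type libraries 2 and 3 had a median position of 0.384 for 293 genes higher and 0.619 for only 24 genes lower. The difference of 0.235 lay between the bounds set for the test. The level of BEAF-32 RNA also stays open. The CTCF control lay at a median position of 0.848 for the genes higher and at 1.45, beyond the scale, for the genes lower. It comes from another culture and treatment, so it cannot settle this.

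Mutant library 1 stood apart from mutant libraries 2 and 3, with reads in many genes that were silent in the other libraries. Dilution by cells that lack hemocyte markers was considered for 164 of 1078 abundant genes at least 2-fold lower there (median ratio 0.358). Such a dilution would hold hemocyte markers at ratios of 0.5 or less. Of 20 tested markers 13 lay above 0.5, with a median of 0.894 over the 20, which goes against dilution alone. The lower quartile was 0.343, so other markers lay under the bound. Of the 15 most abundant 11 lay above it, with a lower quartile of 0.528 and a median of 0.898. As the markers spread across the bound in 1 library, dilution stays open. Silent genes were 1702 protein-coding genes without overlap, chosen for at most 1 read in the 5 other libraries together. Low values elsewhere therefore follow from the choice, which was not repeated around another library. These genes had 2.68 reads per kb in mutant library 1 against at most 0.0979 elsewhere. Reads from genomic DNA could account for part of them. Their reads followed exon length with a rank correlation of 0.469, and those on X held 1.67 reads per kb against 2.88 on autosomes (ratio 0.580), which leaves this open, as the copy number of X was not measured. In 8 homeotic and neuronal genes the reads were 1.55 times that background plus the level of mutant libraries 2 and 3 (quartiles 0.908 to 2.19), also open.

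After CTCF knockdown, genes past the size rule may lie near each other because boundaries between neighbours were lost, which is a hypothesis. With Hsp70 copies left out, 4 of 32 genes had another within 2 places, the pairs CG13692 with BBS8 and AttD with CG43175, and 1.38% of 10000 random draws reached that number. With Hsp70 copies kept in, which count 1 family several times, 13 of 38 protein-coding genes past the rule overlap another gene (34.2%). Among all protein-coding genes that could pass the share was 53.4%. In the annotation used here, which need not be the authors', this argues against reads shared between overlapping genes as the cause of the set as a whole. It decides nothing for the 13 that overlap, among them CG43175. Shared expression of neighbours for other reasons was not tested, and the knockdown has 1 library.

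The 6 libraries of the Beaf lines allow 10 splits of 3 against 3, too few for a share under 0.05. All 10 splits gave 0 genes past limma's adjusted threshold, the highest other also 0, where limma had 1274 genes at an unadjusted p under 0.05 and DESeq2 called 220. For unadjusted genes 1 split, the real one, reached 1274, and the highest other gave 110. For lists called by camera 1 split reached the real 11, and the highest other gave 10. For head-to-head genes 1 split reached the real p of 0.000750 by limma's camera, and the smallest other was 0.00524. Further splits that set wild-type library 1 against mutant library 1 gave 0.00635, 0.00715, 0.00817 and 0.22. Splits that put those libraries together gave 0.141 to 0.653.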
